A study of Mus musculus with 2 samples.

How the data were processed

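DNase I hypersensitivity was measured by sequencing (DNase-seq) in the spleens of 2 male mice aged 2 months, which the labels describe as F1 offspring of the inbred strains C57BL/6J and CAST/EiJ. DNase I cuts accessible chromatin, so the density of cuts along the genome shows where regulatory DNA is open. The labels give each library its own animal and its own biological replicate number, and both belong to 1 group. Here they are called animal 1 and animal 2, after those numbers. The design has no second condition, so each measurement was made in each animal on its own and the animals were set side by side. A mean ± SD with n = 2 describes these animals only.

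Per the deposited file listings, each library was aligned to mm10 and its peaks, footprints and cut-rate intervals were derived from that library alone, not from pooled reads. The aligner, peak caller, footprint caller and their thresholds are not given in the sources used here. The authors deposited 2 peak lists per library in narrowPeak form, in which only the position and the height differ between peaks. The height is a signal, the density of DNase cuts at the peak, and its unit is not stated in words. Tested on the values, every height was a whole multiple of 1 step per library, within 0.01 of a step, and the steps were 0.00716 in animal 1 and 0.00679 in animal 2. If a height counts cuts per M cuts of its library, those steps correspond to totals of 139.6 and 147.3 M cuts. On that reading the lowest peaks held 8 and 6 cuts and the median peak held 124 and 155. Heights of the animals were set side by side as the authors deposited them, and counting error was not modelled since the cut totals are inferred.

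The deposited cut-rate files give a false discovery rate, a q-value, for each short interval, and tested on the files they list only intervals under 0.05. Every peak of the longer list overlapped a listed interval, with a best FDR of at most 0.0499 in animal 1 and 0.0500 in animal 2. The peaks of the shorter list all had a best FDR under 0.001. The longer list is used throughout, and the shorter one is an alternative. The deposited footprint files hold positions and the constant 0.01 in the column for an FDR or p-value, so footprints cannot be ranked.

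All intervals lie on chromosomes 1 to 19, X and Y, and none passes a chromosome's end in the GRCm38.p6 assembly, which has the sequence of mm10. Genes and transcription start sites (TSS) are from GENCODE M21, with 21938 protein-coding genes. A promoter was the 1 kb on each side of any annotated TSS of a gene, and a gene's promoter height was that of its strongest overlapping peak. Such a peak may also overlap the promoter of a neighbouring gene and then counted for both, so a height need not belong to the gene named. A peak's class was set by its midpoint, in the order promoter, exon, intron and intergenic. Distal peaks of a gene had their midpoint over 1 kb and at most 50 kb from its most 5' TSS. A peak counted as found in the other animal when it overlapped a peak there by 1 bp or more. For chance overlap, lists were shifted 100 times along each chromosome with wrap-around. Correlations of heights are across peaks matched 1 to 1, which are not independent replicates, and carry no p.

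The gene lists, motif consensus sequences, tests and most alternatives were chosen before the data were examined. The 25 lists of genes by name cover cell types of the spleen, general processes and cell types of other tissues, and 411 of 412 symbols were found in the annotation. A further list holds the 1466 olfactory and vomeronasal receptor genes. Promoter peaks were tested per animal by a two-sided Fisher's exact test of each list against all other protein-coding genes. Distal peaks were tested by the list median against 10000 random lists of the same size, as a two-sided permutation p. Benjamini-Hochberg adjustment covered the 26 lists, and a call needed an adjusted p under 0.05 in the same direction in both animals. Between the animals, a list's median log2 ratio of promoter heights was placed among 10000 random lists matched on mean height. That percentile describes the pair of libraries and is not a test of animals.

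For motifs, each footprint with its midpoint in a peak was widened by 5 bp on each side and paired with a random window of equal width in the same peak that touched no footprint. Matches to 30 consensus sequences on either strand were compared by a two-sided Fisher's exact test, adjusted over the 30 motifs, with the same rule for a call. The test ignored the pairing and treated windows as independent, although peaks with a footprint held 2.80 and 2.81 of them on average. Its p is therefore approximate, can be too small and describes the windows of 1 library. A control window was found for 94.1% of the footprints in peaks in animal 1 and for 88.9% in animal 2. Footprints with no such window were left out.

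Genes were named in the text by a rule fixed in advance. From each list of spleen cell types, MHC class II, interferon, immediate early or circadian genes, it takes the 2 members with the highest mean promoter height, the first 2 in list order with no promoter peak in either animal, and up to 2 with a peak in 1 animal only. From lists of other tissues it takes up to 3 members with peaks in both animals. Over all genes it takes the 5 highest and the 5 with the largest height ratio in each direction, and it adds 10 loci fixed by name. Some of the genes it selects are not reported here. For motifs it takes the 5 with the highest odds ratio, those with no call and those of other tissues.

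The list tests, the overlap, the matching of peaks and the motif test were first run on simulated data. Among simulated promoter lists of 18 genes, 40 of 40 with added peaks, 36 of 40 with peaks removed and 0 of 40 unchanged lists were called. For distal peaks, 32 of 40 lists with 6 peaks added per gene, 40 of 40 lists set to no peaks and 0 of 40 unchanged lists were called. In these promoter and distal simulations the animals were drawn independently, whereas the real animals shared most open genes. The 0 of 40 therefore does not give the rate of false calls in the data. For the ratio between animals, 31 of 40 lists lowered by 0.3 on the log2 scale and 30 of 40 raised by it lay outside the middle of the random lists, as did 4 of 40 unchanged lists. All 15 motifs planted in 0.300% of windows were called and 0 of the 15 others. Both simulated sets had the same base composition, whereas real footprints had more GC than their control windows (58.5% against 54.8% in animal 1). The 0 of 15 therefore does not give the rate of false calls in the data either. The planted share also exceeded that of several motifs, such as MEF2, matched in 0.0480% of the footprints of animal 1. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

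Alternatives covered the other peak list, the higher 50% of the peaks, reciprocal overlap of 50%, other promoter and distal distances, the most 5' TSS only, random lists matched on neighbouring TSS, quantile-normalized heights, other footprint widths, footprints away from promoters, control windows matched on GC content, stricter FDR levels and each animal left out. Added after seeing the data were random lists matched on promoter CpG content or on GC content, autosomes only, distal peaks over 1 kb from every TSS, footprints in matched peaks only, and height ratios within 2 kb. Reads, alignments and alleles were not analysed here.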

Results

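Open chromatin was mapped by DNase-seq in the spleen, a lymphoid organ that also filters blood and removes old red cells, from 2 male F1 hybrid mice aged 2 months. The group holds 2 animals and there is no contrast between conditions. The values therefore describe the adult spleen and how far its accessible sites were the same in the 2 mice. The longer deposited list held 79246 peaks in animal 1 and 77231 in animal 2, or 78239 ± 1425 (SD, n = 2). The median peak was 200 bp wide in animal 1 and 180 bp in animal 2, and the peaks covered 15.7 and 14.2 Mb. The authors' peak height had a median of 0.888 in animal 1 and 1.05 in animal 2.

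Most accessible sites were shared by the spleens. Of the peaks of animal 1, 76.5% overlapped a peak of animal 2, and of those of animal 2, 79.0% overlapped a peak of animal 1. Circularly shifted lists overlapped by 1.16% and 1.19% on average and by at most 1.37% and 1.33%. In base pairs, 10.8 Mb were covered in both animals, a Jaccard index of 0.563. Sharing depended on height: in the lowest 10% of the peaks 24.997% of those of animal 1 and 17.1% of those of animal 2 were found in the other spleen, against 99.96% and 99.7% in the highest 10%. Over 58266 peaks matched 1 to 1, the log2 heights had a Pearson r of 0.96 and a Spearman rho of 0.945 across peaks. Promoter peaks had a Pearson r of 0.98 and peaks elsewhere one of 0.92. Matched peaks were higher in animal 2, with a median log2 ratio of 0.23 (SD 0.41 across peaks), and 2.40% differed by over 2-fold.

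**Figure D1:**
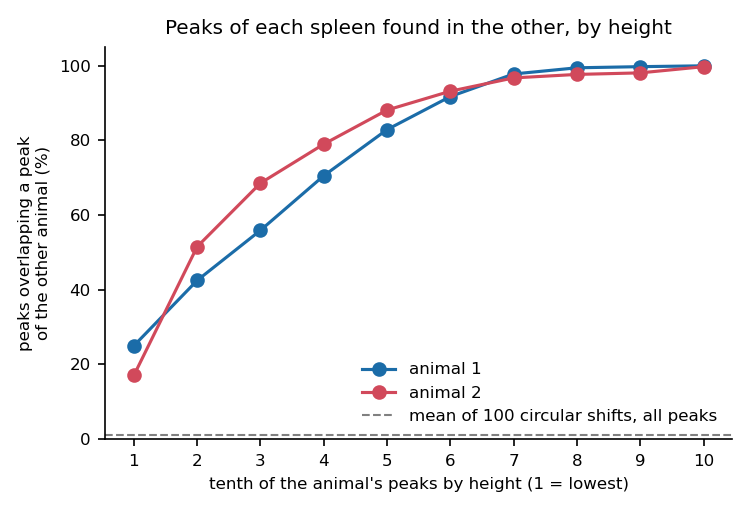
Share of each animal's peaks that overlapped a peak of the other animal (vertical axis, percent) by height, in 10 equal groups of its own peaks (horizontal axis, 1 = lowest), with the mean of 100 circular shifts over all peaks as a dashed line. The share runs from 24.997% and 17.1% in the lowest group to 99.96% and 99.7% in the highest.

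Promoters were the most enriched class of sites. Peaks with their midpoint within 1 kb of a TSS of a protein-coding gene made up 32.5% of the list in animal 1 and 34.7% in animal 2, a mean of 33.6% ± 1.58 (SD, n = 2). That was 8.25 and 8.84 times the share in shifted lists, whose highest value was 4.45%. Exons held 4.05% ± 0.404, introns 28.7% ± 1.82 and intergenic DNA 33.7% ± 0.167 (SD, n = 2 each). Intergenic peaks were at 0.574 and 0.570 times their share in shifted lists. The median promoter peak was 2.34 times as high as the median peak elsewhere in animal 1 and 2.30 times in animal 2.

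At least 1 promoter peak was found for 13473 of 21938 protein-coding genes in animal 1 (61.4%) and for 13728 in animal 2 (62.6%). The same 13116 genes had one in both animals and 969 in only 1 of them. The highest mean promoter height belonged to Dynlt1b, a dynein light chain gene with close paralogs on chromosome 17, at 59.8 ± 2.72 (SD, n = 2), with its peak from 6430021 to 6430180, 11 bp from the TSS. Gm21887 on X followed at 35.4 ± 1.53. Sugct and Mplkip, whose starts overlap on chromosome 13, share a peak of 34.8 ± 3.74 from 17694901 to 17695100, so the height cannot be given to either gene alone. Fzr1, an activator of the anaphase-promoting complex, stood at 32.2 ± 4.40 (SD, n = 2).

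In the main setting B cell genes, and after them T cell genes, had the most complete promoter accessibility among the lists of spleen cell types. All 18 B cell genes had a promoter peak in both animals, against 61.4% and 62.5% of the other genes (Fisher's exact test, adjusted p = 0.00124 and 0.00113). Cr2, the complement receptor of mature B cells, reached a height of 12.4 ± 0.620 at a peak on chromosome 1 from 195176661 to 195176860, across its TSS at 195176716. Pax5, the transcription factor that fixes B cell identity, reached 12.2 ± 1.12 at an intronic peak on chromosome 4 from 44704441 to 44704740, 585 bp from an internal TSS. Cd79a, part of the B cell receptor complex, stood at 9.16 ± 0.287 (SD, n = 2 each). Of 23 T cell genes, 20 had a promoter peak in animal 1 and 21 in animal 2 (Fisher's exact test, adjusted p = 0.0201 and 0.00855). Their heights were lower, with a list median of 1.34 against 5.07 for B cell genes. Foxp3, the regulator of regulatory T cells, was highest at 9.09 ± 1.37, from an intronic peak with its midpoint 717 and 767 bp from a TSS. Within 500 bp of a TSS Foxp3 had a mean height of only 0.880. The kinase gene Lck followed at 5.99 ± 1.37. Cd3e stood at 0.884 ± 0.0651 and Cd8a at 0.764 ± 0.158 (SD, n = 2 each). Cd4 and Ctla4 had no promoter peak in either animal, and Tcf7 had one in animal 2 only, of height 1.34. The T cell call was lost with the shorter peak list, where Fisher's exact test gave an adjusted p of at most 0.0806, and with the higher 50% of the peaks, where it gave one of at most 0.578.

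All 9 genes of MHC class II presentation had a promoter peak in both animals, with a median height of 10.8. The exact test passed in animal 1 (adjusted p = 0.0284) and missed in animal 2 (adjusted p = 0.0512), so the list was not called, although a list of 9 genes can show no stronger result. It passed in both with promoters of 500 bp (exact test, adjusted p = 0.0276), the higher 50% of the peaks (0.00751) and the shorter list (0.0222), and it missed within 2 kb and with the most 5' TSS only. H2-DMa and H2-Ab1, which encode chains of class II molecules or their peptide loader, stood at 16.7 ± 0.00813 and 13.2 ± 0.554 (SD, n = 2 each), the former from a different peak in each animal. Of the 12 germinal centre and plasma cell genes 10 were open in both animals, which did not pass (exact test, adjusted p = 0.190 and 0.286). Mef2b reached 16.4 ± 2.03 and Derl3 14.7 ± 3.46, while Jchain and Tnfrsf17, both used by plasma cells, had no promoter peak.

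Genes of the other resident cell types were open in smaller numbers and were not called as groups in either direction, apart from megakaryocytes and neutrophils. With the higher 50% of the peaks, macrophage (exact test, highest adjusted p = 0.00333) and stromal genes (0.0191) were called as open less often. Of 21 macrophage and monocyte genes, 9 had a promoter peak in both animals and 5 in animal 1 only, Csf1r and C1qa among them with heights of 0.523 and 0.437 there. Hmox1, the haem-degrading enzyme of red pulp macrophages, stood at 2.68 ± 0.687 and Cd68 at 2.00 ± 0.480. Adgre1 and C1qb had no promoter peak in either animal. Spic, the factor that red pulp macrophages need, had 0.487 ± 0.112, and Spi1, which encodes PU.1, had 6.397 ± 0.335 (SD, n = 2 each). Among dendritic cell genes, 7 of 12 were open in both animals, led by Irf8 at 7.97 ± 0.484 and Tcf4 at 6.75 ± 1.84. Clec9a and Xcr1 had no peak and Siglech had one in animal 1 only. Of 12 NK and cytotoxic cell genes 6 were open in both animals, led by Prf1, the perforin gene, at 1.74 ± 0.220 and Klrd1 at 0.993 ± 0.328. Ncr1 and Klrb1c had none.

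Blood-forming and structural cells gave a mixed picture. Of 20 erythroid genes 8 were open in both animals, led by Bpgm at 18.5 ± 2.11 and the transferrin receptor gene Tfrc at 15.3 ± 0.585, both of which other cells use too. Gata1 and Hba-a1 had no promoter peak, and Klf1 and Ank1 had one in animal 2 only, of heights 0.665 and 0.312. Fewer megakaryocyte genes than other genes were open, 4 of 14 in each animal (Fisher's exact test, adjusted p = 0.0413 and 0.0218), a call lost within 2 kb (exact test, adjusted p = 0.220), with the higher 50% of the peaks (0.125) and with the shorter list (0.0806). The open ones included Itga2b at 7.68 ± 0.474 and Gfi1b at 4.25 ± 0.446, while Gp1ba and Gp1bb had none. Neutrophil genes were also open less often, 4 of 15 in animal 1 and 2 of 15 in animal 2 (exact test, adjusted p = 0.0176 and 0.000654). Mmp9 and Cebpe had peaks of 2.39 ± 0.851 and 0.542 ± 0.0879, Csf3r and Padi4 had one in animal 1 only, and S100a8 and S100a9, which encode abundant neutrophil proteins, had none. Stem and progenitor cell genes were open in both animals for 7 of 10, with Runx1 at 6.66 ± 0.561 and Meis1 at 2.92 ± 0.545. Cd34 and Gata2 had peaks in animal 2 only and Hoxa9 had none. Endothelial genes were open in both animals for 6 of 15, with Pecam1 at 3.39 ± 0.256 and Cdh5 at 2.58 ± 0.413. Tie1 and Flt1 had peaks in animal 1 only, and Tek and Sox18 had none. Stromal genes were open in both animals for 10 of 20, with Col1a1 at 2.94 ± 0.766. Pdgfrb and Dcn had none, Col3a1 had one in animal 1 only, and Tlx1, the homeobox gene needed for spleen development, had 0.515 ± 0.0594 (SD, n = 2 each).

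General gene sets were open throughout. Every member of the ribosomal protein (24), immediate early and stress (18), cell cycle (16), proteasome (14) and circadian (12) lists had a promoter peak in both animals, and Fisher's exact test called each list, with adjusted p from 0.000150 to 0.0128. Jund and Klf2 led the immediate early genes at 20.5 ± 1.74 and 19.1 ± 1.53, and the clock genes Per1 and Dbp stood at 19.1 ± 0.589 and 18.3 ± 0.403 (SD, n = 2 each). Of 18 interferon-stimulated genes 14 were open in both animals (exact test, adjusted p = 0.125 and 0.286), with Stat2 at 11.6 ± 2.08 and Usp18 at 7.20 ± 1.59. Ifit3 and Oas1a had no promoter peak and Oas2 had one in animal 1 only.

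Genes of other tissues were mostly closed, as were the megakaryocyte and neutrophil genes of the spleen. Only 1 of 19 hepatocyte genes had a promoter peak, Apob at 0.446 ± 0.0226 (exact test, adjusted p = 5.58e-06 and 3.27e-06). Of 16 pancreatic acinar genes 2 did, Bhlha15 at 3.30 ± 0.550, a gene that plasma cells use as well, and Rbpjl at 3.18 ± 1.07 (exact test, adjusted p = 0.000516 and 0.000347). Among keratinocyte genes 4 and 5 of 18 had one (exact test, adjusted p = 0.00322 and 0.00735), with Krt10 at 4.15 ± 0.321, Grhl3 at 0.5005 ± 0.262 and Krt1 at 0.484 ± 0.00632 (SD, n = 2 each). Olfactory and vomeronasal receptor genes were open at 13 of 1466 in animal 1 and 14 in animal 2, with Vmn1r4 highest at 8.83 ± 1.44, then Olfr433 at 1.81 ± 0.389 and Olfr658 at 1.39 ± 0.687. Neuronal genes were open at 7 and 8 of 17 and were not called (exact test, adjusted p = 0.181 and 0.286), with Gad1 at 1.58 ± 0.330 from a different peak in each animal, Rbfox3 at 1.44 ± 0.409 and Grin1 at 1.04 ± 0.256. Muscle genes were open at 7 and 4 of 19 (exact test, adjusted p = 0.0550 and 0.00132), with Ckm at 4.63 ± 0.663, Myl2 at 1.33 ± 0.482 and Ryr2 at 1.04 ± 0.321. Male germ cell genes were open at 6 and 7 of 19 (exact test, adjusted p = 0.0201 and 0.0512), and Tex14 at 14.2 ± 1.079, Zpbp at 8.21 ± 1.90 and Dazl at 7.24 ± 1.25 were the highest (SD, n = 2 each).

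Several of these heights depend on how a promoter is drawn. With the most 5' TSS only, Itga2b, Mmp9, Cdh5, Krt10, Krt1, Rbfox3, Myl2 and Spic had no promoter peak in either animal, and the mean heights of Pax5 and Lck were 4.40 and 2.56. Within 500 bp Mmp9 had 0.913, Gad1 0.908 and Apob 0.146, and Cebpe and Rbfox3 had none. Within 2 kb Klf1 reached 7.18, Gad1 2.47, Padi4 2.17, Cebpe 1.83 and Klrb1c 1.46. Cebpe, Apob, Grhl3, Krt1, Cd3e, Cd8a, Spic and Tlx1 had no promoter peak among the higher 50% of the peaks.

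Promoter CpG content differs between these lists, and a permutation test against random lists matched on it, chosen after seeing the data, changed several calls. B cell, T cell, ribosomal protein and olfactory lists passed in both animals as before, and MHC class II (adjusted permutation p = 0.0013 in both) and interferon-stimulated genes (0.0052 and 0.0312) passed as well. Among genes of like CpG content 33.6% had a promoter peak for the B cell list and 31.5% and 30.9% for the class II list, against 100% of the members. The immediate early (highest adjusted permutation p = 0.0780), cell cycle (0.576), circadian (0.493), proteasome (0.358), hepatocyte (0.0550), acinar (0.251), keratinocyte (0.640), neutrophil (1.00) and megakaryocyte (1.00) lists were not called there.

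**Figure D2:**
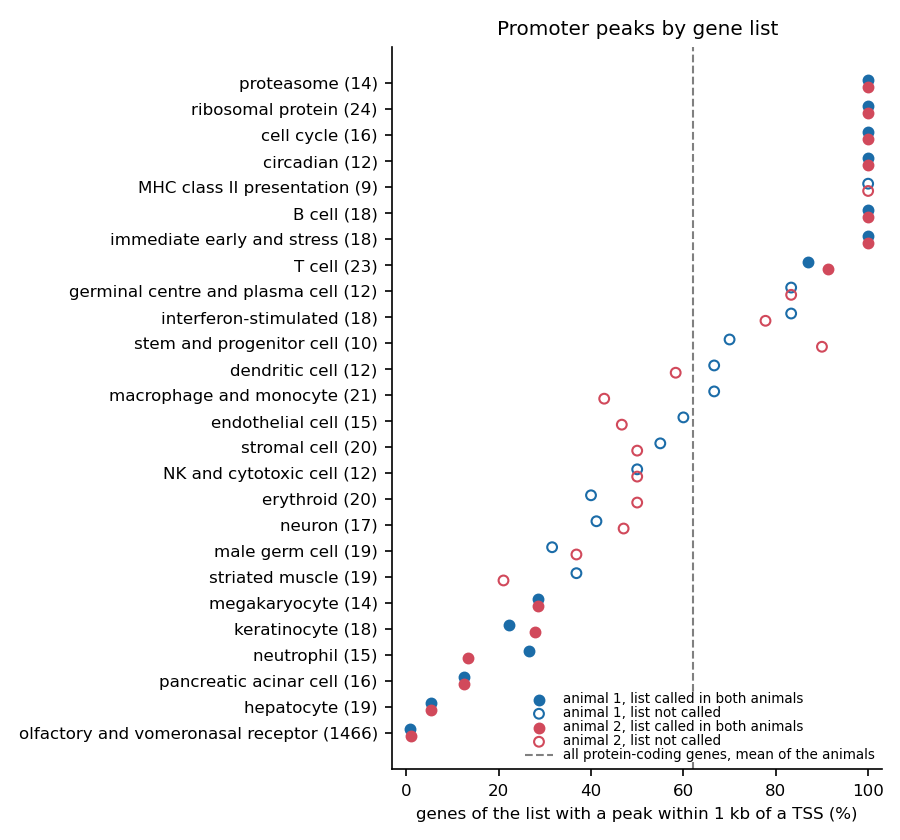
Share of the genes of each list with a peak within 1 kb of a TSS (horizontal axis, percent), 1 point per animal, with list sizes in brackets, filled points for lists called by Fisher's exact test in both animals and a dashed line at the share of all protein-coding genes. All 18 B cell genes were open in both animals, against 1 of 19 hepatocyte genes.

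Distal elements were dense around class II, immediate early, B cell and ribosomal protein genes. B cell genes had a median of 14 peaks between 1 and 50 kb from their most 5' TSS in animal 1 and of 12 in animal 2, against 4.5 in random lists (permutation test, adjusted p = 0.00104 and 0.00312). Genes of MHC class II presentation, which lie close together on chromosome 17 for the most part, had medians of 24 and 29 (permutation test, adjusted p = 0.00104 and 0.0013). Neighbouring members count many of the same peaks, and random lists were drawn gene by gene. The permutation p can therefore be too small for a list of clustered genes. Immediate early genes had 18 and 16 and ribosomal protein genes 13.5 and 13, with the same adjusted permutation p as class II genes, which rests on the smallest p that 10000 lists can give. Olfactory and vomeronasal receptor genes had a median of 0 in both animals and were called lower. T cell genes had 10 in animal 1 and 7 in animal 2 and passed in animal 1 only (permutation test, adjusted p = 0.0173 and 0.381). The ribosomal protein call ended when peaks within 1 kb of any gene's TSS were left out (highest adjusted permutation p = 0.0666). No other list was called. By locus, the numbers of peaks within 50 kb in animals 1 and 2 were 26 and 22 at Pax5, 13 and 15 at Cd79a, and 19 and 16 at Cd3e. Cd4, with no promoter peak, had 17 and 18 around it. Cd8a had 8 and 6, Spi1 11 and 13, Spic 8 and 7, Tlx1 11 and 9, and Gata1 2 and 3.

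**Figure D3:**
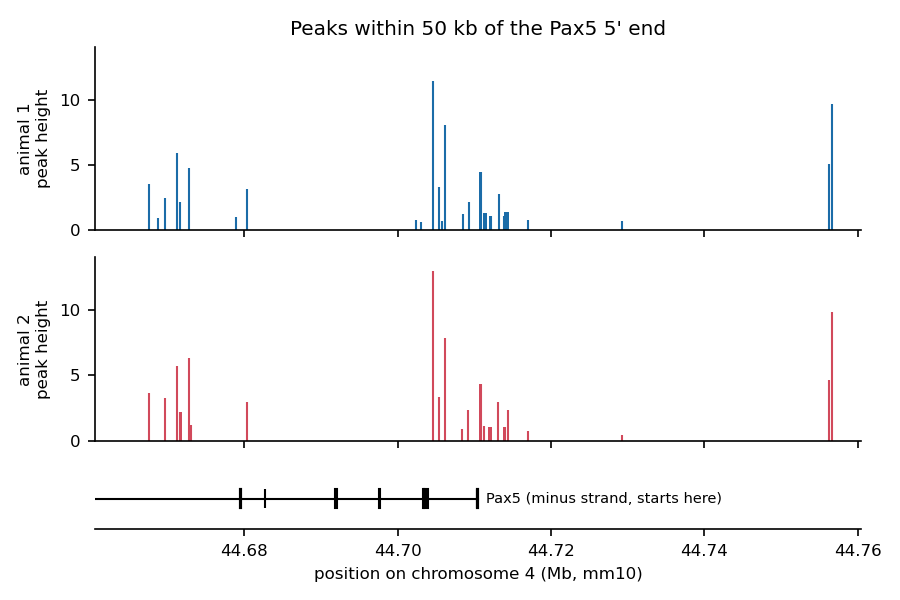
Peaks within 50 kb of the most 5' TSS of Pax5 on chromosome 4 (horizontal axis, Mb in mm10), with the authors' peak height on the vertical axis for each animal and the annotated exons below. The tallest peak lies in an intron from 44704441 to 44704740, at 11.4 in animal 1 and 13.0 in animal 2, and the region holds 26 and 22 peaks.

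Promoter heights differed in a patterned way between the 2 libraries. Over the 13116 genes open in both, promoters were higher in animal 2 by a median log2 ratio of 0.27 (SD 0.29 across genes). B cell promoters had a median ratio of -0.05, T cell promoters -0.02 and class II promoters -0.22, each at or below the 0.0200 percentile of random lists of like height, whose medians were 0.28, 0.31 and 0.26. Macrophage and monocyte (-0.04, percentile 0.76), immediate early (0.06, percentile 0.16) and ribosomal protein promoters (0.11, percentile 0.65) also lay low. Cell cycle promoters lay high (0.41, percentile 97.9). The other 16 lists with enough genes to compare lay in neither tail of the random lists, though NK and cytotoxic cell promoters lay low within 2 kb (percentile 1.04). These percentiles describe 1 library per animal and do not test a difference between mice.

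A difference of over 2-fold from the median ratio was found at 77 genes. The largest log2 ratios in favour of animal 2 were at Smad6 (2.71), Gm11168 (2.58), Psd (2.16), Wnt7a (1.66) and Nipa1 (1.43). Within 2 kb of a TSS the ratio was 0.75 for Smad6, -1.02 for Gm11168 and -0.10 for Psd, so those values depended on the distance allowed. For Smad6 and Psd the strongest peak of animal 2 lay at the 1 kb limit, with its midpoint 1032 and 1035 bp from the TSS, while that of animal 1 was another peak. In favour of animal 1 were P2ry10 (-1.57), a receptor gene on X, the histone genes Hist1h3i (-1.53) and Hist1h3d (-1.49), Noxred1 (-1.46) and 9430069I07Rik (-1.35). Within 2 kb Hist1h3d had -0.08, and the value of 9430069I07Rik sets different peaks of the animals side by side.

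Footprints, the short protected stretches that bound proteins leave within open chromatin, numbered 211394 in animal 1 and 215907 in animal 2, or 213650 ± 3191 (SD, n = 2). Their median width was 10 and 11 bp, and 84.9% and 83.6% of them lay in peaks. Of the peaks, 81.4% and 83.5% held at least 1, and peaks with a footprint had a median height of 1.10 and 1.28 against 0.415 and 0.448 for those without. Of the footprints, 59.4% of those of animal 1 and 56.7% of those of animal 2 overlapped a footprint of the other spleen. In shifted lists at most 0.281% and 0.271% did. These shares are below those of peaks, but footprints are much narrower, so the 1 bp rule does not treat the 2 kinds alike.

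CTCF, the insulator protein, had the highest finite odds ratio in footprints. Its consensus was matched in 2.23% of footprints and 0.0195% of control windows in animal 1 and in 1.95% and 0.0143% in animal 2, odds ratios of 117 and 139. They were 491 and 1338 with no bases added and 50.1 and 73.2 with 10 bp added, and with GC-matched windows NRF1 exceeded CTCF in animal 1 (152 against 107). In the main setting NRF1 had odds ratios of 93.2 and 89.8 and CRE, the site of CREB and ATF proteins, 18.1 and 16.3. RFX and REST matches were rare, in 0.0101% and 0.0107% of the footprints of animal 1, and absent from its control windows, and both were called (exact test, highest adjusted p = 0.000488 and 1.35e-05). Lineage motifs of the spleen were led by EBF, the site of the B cell factor EBF1, at 6.998 and 7.81. ETS (3.27 and 2.43), RUNX (2.35 and 1.61), IRF (1.92 and 1.19), NF-kB (1.68 and 3.71), SP/KLF (8.40 and 8.15), KLF CACC (2.10 and 1.81), NFY (1.10 and 1.47) and the E-boxes CAGGTG (1.17 and 1.12) and CAGATG (1.13 and 1.07) were also called more frequent in footprints by Fisher's exact test, 15 motifs in all. With no bases added to the footprints the calls of RUNX (exact test, highest adjusted p = 0.226), IRF (0.627) and NFY (0.114) ended, as did those of RFX (0.0558), NFY (0.302) and CAGATG (0.0902) away from promoters. The CAGATG call also ended with 10 bp added (exact test, highest adjusted p = 0.49954) and in matched peaks (0.564).

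Fewer matches in footprints than in control windows were called for 4 motifs. FOXA, a site of liver and endodermal factors among others, had odds ratios of 0.357 and 0.315, and GATA, a site of erythroid and T cell factors among others, had 0.566 and 0.537. TEAD had 0.720 and 0.817 and the E-box CAGCTG 0.894 and 0.935, and with 10 bp added neither was called (exact test, highest adjusted p = 0.5001 and 0.0508). CAGCTG was also not called with no bases added (0.714), nor TEAD away from promoters (0.191), by the same exact test. Of the motifs chosen for factors of other tissues, HNF4A, HNF1 and GRHL were not called. The HNF1 consensus was not matched in a single footprint or control window. FOXA and TEAD of that class were called less frequent, but REST and CAGATG, listed here as the NEUROD E-box, were called more frequent. The class was fixed with the list of motifs, and a consensus match does not identify the factor bound. Several lineage motifs passed in animal 1 only: octamer (1.90 and 1.10; exact test, adjusted p = 4.86e-13 and 0.449), MEF2 (3.24 and 1.05; 8.36e-08 and 0.941), PU.1 (1.36 and 0.892; 5.69e-09 and 0.0695), the ETS-IRF composite (1.48 and 0.944; 6.63e-08 and 0.594) and TCF/LEF (1.44 and 1.03; 0.00271 and 0.908). With no bases added PU.1 was instead called less frequent in both animals (0.690 and 0.448; exact test, adjusted p = 0.000739 and 3.69e-13), as was AP-1 (0.751 and 0.762; 0.0065 and 0.00754). YY1 (1.40 and 1.80) and AP-1 (0.977 and 0.870) passed in animal 2 only, and STAT (0.945 and 0.811) in neither. With control windows of like GC content all of the former group and YY1 were called in both animals, while TEAD (pooled odds ratio 1.05) and the E-box CAGGTG (0.962) were not. Footprints come from cut patterns, which depend on sequence preferences of DNase I as well as on bound protein.

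**Figure D4:**
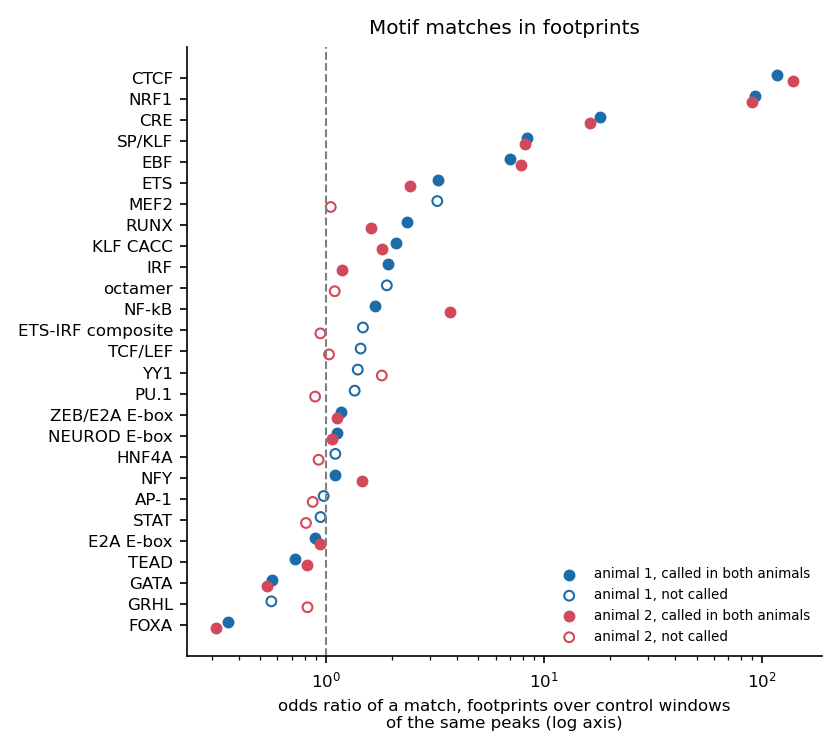
Odds ratio of a consensus match in footprints over control windows of the same peaks (horizontal axis, log scale), 1 point per animal, filled where Fisher's exact test called the motif in both, with REST, RFX and HNF1 left out for want of a finite ratio. CTCF lies at 117 and 139 and FOXA at 0.357 and 0.315.

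The X chromosome, of which males have a single copy, had the fewest peaks per Mb apart from Y. It held 13.3 peaks per Mb in each animal, against 32.1 and 31.3 on the autosomes together, ratios of 0.415 and 0.426. The lowest autosome, chromosome 14, had 23.5 and 23.4 and the highest, chromosome 11, had 50.7 and 49.1. Promoter peaks of X were also lower, with medians of 1.13 and 1.17 against 1.75 and 2.00 on the autosomes, and below the lowest autosomal medians of 1.39 and 1.60. The Y chromosome had 85 and 93 peaks, under 1.06 per Mb in both.

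**Figure D5:**
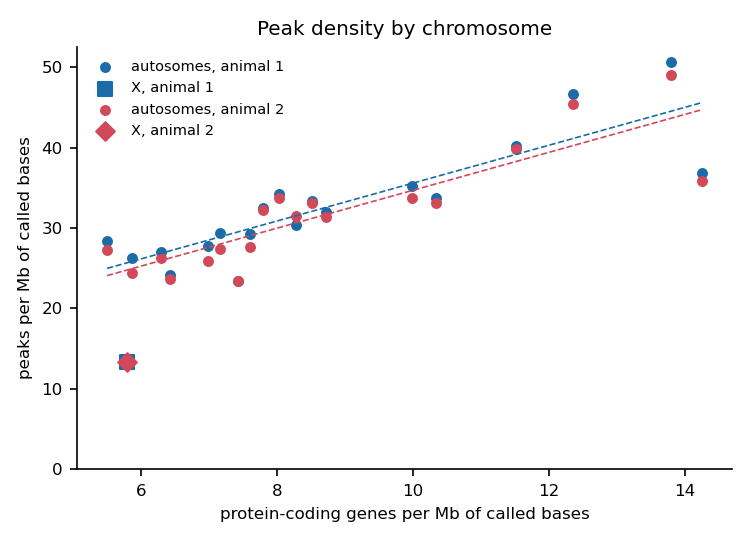
Peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for each autosome and X, in both animals, with dashed least-squares lines through the 19 autosomes. X lies at 13.3 peaks per Mb, below every autosome.

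The authors' cut-rate file marked 27.6 Mb under an FDR of 0.05 in animal 1 and 24.3 Mb in animal 2, of which 76.6% and 87.0% were marked in both. Under 0.01 the lengths were 23.1 and 20.2 Mb and under 0.001 they were 19.1 and 16.9 Mb. The Jaccard index of the marked bases went from 0.688 at 0.05 to 0.715 at 0.01 and 0.728 at 0.001.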

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

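Of the tests of explanations here, the predictions for GC-matched control windows, for the X promoter heights and for the macrophage list were chosen after the result was seen. Groups of 2 animals are too small for a search for outlying samples, and there are no groups to set against each other.

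The shorter deposited peak list, which the main text uses only as an alternative, holds peaks that the longer list lacks although its FDR is stricter. There were 714 such peaks in animal 1 and 486 in animal 2, or 1.29% and 0.930% of the shorter list. Their median heights were 0.544 and 0.686, 94.5% and 97.3% lay within 500 bp of a peak of the longer list, and 69.2% and 68.3% were in promoters.

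B cell, T cell and class II promoters were lower in animal 2 than random lists of like height. Base composition was argued against: with random lists matched on height and GC content, the highest of the 3 percentiles was 0.19. A smaller share of lymphocytes in animal 2 remains a candidate explanation, since distal peaks within 50 kb of B cell and T cell genes were also low there, at percentiles of 1.41 and 1.75. It would raise macrophage sites, and their promoters were instead low at a percentile of 1.74, which argues against it for that list, while distal peaks near the same genes were not, at 62.8, so the cause stays open. The low promoters were not particular to lymphocyte lists. With random lists matched on height and GC content, immediate early promoters lay at a percentile of 0.07 and ribosomal protein promoters at 1.25. Distal peaks near those genes lay at 3.27 and 19.35. With 1 group in the design no other biological explanation was tested, and cell numbers were not measured.

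Octamer, ETS-IRF, MEF2 and PU.1 motifs were called in the footprints of animal 1 and not of animal 2. With control windows matched on GC content, 4 of the 4 were called in animal 2, though each odds ratio stayed below that of animal 1. Base composition may therefore account for the missing calls at the threshold. It was not shown to account for the difference between the animals, since footprints had more GC than their control windows in both. Some calls also returned without GC matching, of octamer (1.20) and ETS-IRF (1.19) with 10 bp added and of octamer (1.36) away from promoters. Footprints lying in different peaks were argued against as the whole cause, since 0 of the 4 were called in animal 2 when only peaks matched between the animals were used, though the odds ratios of MEF2 (2.19 and 1.36), PU.1 (1.25 and 0.998) and octamer (1.55 and 1.09) lay closer together there. Footprints widened by 5 bp had a GC content of 59.97% in animal 2 against 58.5% in animal 1. Their control windows had 55.9% against 54.8%. Why the animals differ stays open, with no biological explanation tested.

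Peaks on X were fewer per Mb than on every autosome. A low gene density was argued against as the whole cause, as X lay 1.29 times as far below the line through the autosomes, or further, as the autosome farthest from it. A single copy of X was argued against as the whole cause of the low number, since X peaks over a height of 1 were at most 0.479 times as dense as autosomal peaks over 2, away from promoters. The lower promoter heights of X are consistent with a single copy, at 0.645 and 0.583 times the autosomal median and below every autosome. An F1 male has its X from a single parental strain, and how well reads of either strain align to X was not tested, nor was any other biological explanation.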

How the results depend on the processing

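No promoter list called in 1 direction was called in the other under any alternative. NK genes, not called in the report, were open less often than other genes and more often than genes of like CpG content, also without a call. Against the latter, macrophage genes passed in animal 1 only (adjusted permutation p = 0.0052 and 0.619), and erythroid genes lay lower in animal 1 and higher in animal 2. Peaks over the median height numbered 38953 per animal. Peaks found in the other animal averaged 69.3% with reciprocal overlap of 50%, 88.8% with the higher 50% of the peaks and 83.8% with the shorter list. The height correlation away from promoters had a Pearson r of 0.922 and a Spearman rho of 0.905. The promoter share of peaks was 26.5% within 500 bp, 39.7% within 2 kb and 44.7% for the higher 50% of the peaks. Lists with fewer promoter peaks numbered 6, against 10 with the higher 50% of the peaks and 1 with random lists matched on CpG content, and 2 lists had fewer distal peaks within 100 kb, against 1. Lists higher in animal 2 numbered 2 within 2 kb, against 1, and the added one, neutrophils, had too few genes to compare within 1 kb. Neuronal, striated muscle and male germ cell lists had fewer promoter peaks in both animals with the shorter list and with the higher 50% of the peaks, and macrophage and stromal lists with the latter. So did neuronal and muscle lists with the most 5' TSS only (adjusted exact p = 0.0482 and 0.00493), muscle within 500 bp (0.0283) and germ cell on autosomes only (0.0298). More distal peaks were also called for germinal centre genes within 20 kb or with neighbouring TSS matched and for T cell genes within 100 kb. Footprints found in the other animal were 43.3% with reciprocal overlap. Motifs called less frequent in footprints numbered 2 with 10 bp added and 2 away from promoters, against 4. The density ratio of X was 0.404 away from promoters. The FDR sites covered 21.6 Mb at 0.01 and 17.98 Mb at 0.001. Values that turned direction with a call in either setting were the pooled odds ratios of PU.1 with no bases added (0.560), CAGCTG away from promoters (1.00), CAGGTG (0.962) and TEAD (1.05) with GC-matched windows, and without a test the log2 ratios within 2 kb of Gm11168 (-1.02) and Psd (-0.10) did. AP-1, with no call in both animals in either setting, went from 0.977 and 0.870 to 1.23 and 1.14 with GC-matched windows. Fewer peaks entered the stricter settings and narrower windows hold fewer motif matches; otherwise the cause was not tested. With 1 animal left out, calls rest on the other: 7 to 8 lists had more promoter peaks and 7 had fewer, and 16 to 20 motifs were called more frequent. Of 72 named genes open in both animals, 68 stayed so within 500 bp, 72 within 2 kb, 63 with the most 5' TSS only, 53 with the higher 50% of the peaks and 64 with the shorter list. Ranking footprints by score could not be run, since their file holds a constant. The alternatives matched on CpG or GC content, and those with 2 kb ratios, matched peaks, autosomes only and distance from every TSS, were chosen after seeing the data.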

Other observations

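All values and tests in this part were chosen after seeing the data.

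The antigen receptor loci were open to different degrees. The immunoglobulin light chain locus Igl, on chromosome 16 from 19061618 to 19260859, had 136 peaks per Mb in animal 1 and 90.3 in animal 2, against 26.9 and 25.1 on its chromosome. The heavy chain locus Igh, over 2.75 Mb of chromosome 12, had 140 and 142 peaks, or 51.0 and 51.7 per Mb, against 27.7 and 26.5. Igk on chromosome 6 had 114 peaks in animal 1 and 67 in animal 2, or 35.9 and 21.1 per Mb, against 28.6 and 27.1. Trb on the same chromosome had 24.0 and 22.5 peaks per Mb, and Tra and Trd had 22.8 and 22.3 against 22.8 and 22.7. Trg, with 4 and 2 peaks, had 22.9 and 11.4 against 28.6 and 26.6. The highest Trb peak lay from 41554401 in both animals, with heights of 3.04 and 2.59.

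Among windows of 100 kb, the one with the most peaks on average held Grk2, Pold4, Clcf1 and Rad9a on chromosome 19 from 4200001 (45 and 58 peaks). The next, on chromosome 17 from 34200001, held the class II genes H2-Ab1, H2-Aa and H2-Ob with Psmb8 and Tap2 (41 and 59). A window on chromosome 4 from 3000001, near the start of the sequenced part, held 0 protein-coding genes and 42 and 53 peaks. Windows at Zfp36l2 and Thada (28 and 56), at Gpr183 and Gpr18 (25 and 55) and at S1pr4 and Nfic (23 and 56) had about double the peaks in animal 2. Windows at Mid1 (50 and 32), Hvcn1 (44 and 30) and Mknk2 (40 and 30) had more in animal 1.

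Strong peaks seen in a single animal lay close to peaks of the other. Of the peaks over a height of 3, 17 of 14209 in animal 1 and 200 of 16840 in animal 2 overlapped none in the other animal. Their median distance to the nearest peak of the other animal was 60 and 80 bp and the largest was 160 and 320 bp. The middle 50 bases of the Gm21887 promoter peak, on X near its end, occurred 2 times in the reference, and those of the Dynlt1b peak 1 time.

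Distal peaks near hepatocyte genes had a median log2 ratio between the animals of 0.45, at a percentile of 95.4, in neither tail of the random lists. Those near olfactory and vomeronasal receptor genes had 0.35, at 99.6, and those near class II genes -0.06, at 0.0200. List members that lie close together share distal peaks, and random lists were drawn gene by gene. Percentiles of lists of clustered genes can therefore be too extreme.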
